A study of Homo sapiens with 38 samples.

How the data were processed

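Processed RNA sequencing tables of 6 lymphoma lines, kept for 6 h or 14 days with either HDAC inhibitor or with the solvent, were re-analysed. Per the labels, RNA was taken up in Trizol and libraries were made from 1 µg of total RNA with the Illumina TruSeq RNA kit. The labels name STAR, edgeR and the genome build hg38. Their versions, the annotation release and the strand setting of the counting are not given in the sources used here, nor are the drug doses. The deposited raw table holds read counts per gene as whole numbers, for 37 libraries and 18011 genes. The deposited normalized table holds log2 CPM (counts scaled to a common library size) with effective library sizes from the trimmed mean of M-values (TMM), which were recomputed from the raw counts. All tests below used the raw counts, apart from an alternative run on the deposited normalized values. Gene identifiers were matched to GENCODE 29 on GRCh38, which gave a symbol and a position to 17859 of the 18011 genes and none to the other 152.

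Library totals ran from 3.19 to 8.92 mega counts (M). A count of 0 allows up to 3 counts, which is 0.336 to 0.941 CPM depending on the library, and such floors cover counting error only. The series lists 38 samples. A further sample labelled SUDHL4, vorinostat, 14 days has no column of its own and was not analysed, and SUDHL6 with vorinostat at 6 h was not analysed here. Each line had 1 library per treatment and time, so the line is the replicate. Nothing in the sources states whether the libraries of a line came from separate cultures. With the line as block, p-values measure how treatment differences vary between lines, library noise included. This spread was estimated once per time over all treatments and DMSO sets, so it is not that of each comparison alone. Beyond the block, libraries of a line count as independent, although both drugs shared a line's pattern. At 14 days the titles give a DMSOP and a DMSOV library per line, and each drug was set against the DMSO that carries its first letter. This is a reading of the titles that the labels do not state. In the column names of the normalized table the 6 h DMSO libraries end in V for 4 lines and in P for 2, although their titles say DMSO alone, and at 6 h both drugs were set against these same libraries.

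Genes were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, the default filter of filterByExpr (minimum count 10, minimum total 15), robust quasi-likelihood fits and the cell line as block. Each time was fitted apart. The change of a drug's effect between the times was tested as an interaction in 1 fit of all libraries with line and time together as block. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given with standard errors (SE). The group tests used 37 gene lists fixed before the data were examined. They cover HDACs, histone acetyltransferases and chromatin writers, B-cell stages, cell cycle, DNA repair, cell death, immune, signalling, stress and metabolic pathways, drug efflux, neuronal genes, mitochondrially encoded genes and markers of other cell types. Lists with 5 or more tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Beside it stand camera with an estimated correlation, fry, and the number of members called over all genes and adjusted over the list alone. Groups, comparisons, tests, lists and the naming rule were chosen before the data were examined.

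Genes are named by a fixed rule. For each drug against DMSO it takes the 8 largest rises and the 8 largest falls among genes called with a mean log2 CPM of at least 2 and the same sign in every line, and 5 and 5 for other comparisons. Per list it takes up to 2 called members with the largest rise and 2 with the largest fall. A fixed set of HDAC genes and lymphoma or drug response genes is added whatever their values. The text gives a part of these.

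Fold changes of both drugs were correlated across genes. Unchanged groups set against the same DMSO libraries were simulated to give the value that shared controls produce. Shares of counts were compared by exact paired permutation tests, and the match of drugs within a line by an exact permutation of line labels. Genes at least 2-fold changed were counted in each line, from log2 CPM with a prior count of 2, among genes with a mean CPM of at least 5. The pipeline was tested on simulated data with 200 changed genes per comparison. At 6 h it recovered 68.7% of 2-fold changes with pracinostat and 62.7% with vorinostat, and at 14 days 49.3% and 61.2%. False calls made up 5.48% and 8.63% of the calls at 6 h and 7.62% and 1.85% at 14 days, where the adjustment aims at 5%. The simulated libraries were drawn independently, with the same fold in every line, so no response was shared by the drugs of a line. Far fewer genes were changed than were called in the data. These rates therefore do not show the rates in the real data.

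Alternatives were DESeq2 1.42.0, limma-voom, limma on the deposited normalized values, size factors of DESeq2 or library totals in place of TMM, other filters, 1 fit of both times, no block, both DMSO sets as controls, a 2-fold limit and leaving out each line. After the data were seen, runs without mitochondrial and ribosomal protein genes, without the WSUDLCL2 pracinostat library at 6 h and a leave-one-out run of the line matching were added. Other splits of the libraries were fitted as a check on calls made by chance. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.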

Results

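RNA sequencing profiled 6 established human lines of diffuse large B-cell lymphoma (DLBCL), named OCILY1, PFEIFFER, SUDHL4, SUDHL6, TOLEDO and WSUDLCL2. Cells had been kept with the solvent DMSO, with vorinostat or with pracinostat for 6 h or 14 days. Both drugs are hydroxamic acids that inhibit histone deacetylases (HDACs), the enzymes that take acetyl groups off histones and other proteins. The 6 h series held 6 DMSO, 6 pracinostat and 5 vorinostat libraries, with no vorinostat library of SUDHL6. At 14 days, 5 lines without SUDHL6 each had a library of pracinostat, of vorinostat and of a pair of DMSO sets titled DMSOP and DMSOV. Totals, in mega counts (M), were 3.29 to 8.74 M per library in DMSO at 6 h, 5.00 to 5.96 M with pracinostat and 5.19 to 8.36 M with vorinostat. At 14 days they were 4.49 to 8.92 M in DMSOP, 4.57 to 7.05 M in DMSOV, 4.71 to 8.33 M with pracinostat and 3.19 to 6.97 M with vorinostat. The series title asks about differing sensitivities of DLBCL cells to HDAC inhibitors, and no label gives the sensitivity of a line.

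The comparison of pracinostat with DMSO at 6 h asked which transcripts changed soon after exposure. Of 6 genes that hold back the cell cycle 5 rose, and 19 of 29 genes of B-cell identity, 18 of 25 of ribosome production and 7 of 10 of histone acetylation fell (5, 21, 19 and 7 adjusted over the list alone). Camera called these lists at the preset correlation and 0 of 32 lists with an estimated correlation. CDKN1A (ENSG00000124762, GRCh38 chromosome 6, 36676460 to 36687339), which encodes the cell cycle inhibitor p21, rose from 13.3 ± 6.54 CPM to 58.9 ± 32.0 CPM (SD, n = 6), a log2 fold change of 2.06 (SE 0.28). MYC, which encodes a transcription factor of growth genes, had a log2 fold change of -1.07 (SE 0.19), and the anti-apoptotic gene BCL2 one of -0.94 (SE 0.15). Among the largest rises were CTTNBP2NL (ENSG00000143079, chromosome 1, 112396181 to 112463456, GRCh38) with 3.78 (SE 0.35), RGL1 with 3.67 (SE 0.28) and HEY1, a Notch target, with 3.59 (SE 0.30). The largest falls included METAP1D, a mitochondrial methionine aminopeptidase, with -2.35 (SE 0.19), and DUS3L, which modifies transfer RNA, with -2.41 (SE 0.23). All genes named here changed the same way in 6 of 6 lines.

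In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5289 of 13177 genes changed with pracinostat at 6 h, 2794 of them higher and 2495 lower. Scaling by library totals moved that split to 3556 higher and 1929 lower and the median of all genes from 0.03 to 0.13, and a 2-fold limit gave 1045 higher and 605 lower. Without the cell line as block, 577 genes were called.

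Vorinostat at 6 h gave the same picture for these genes, with 5 lines. CDKN1A rose by a log2 fold change of 2.22 (SE 0.30), MYC changed by -1.01 (SE 0.20) and BCL2 by -1.02 (SE 0.16). RGL1 rose by 4.16 (SE 0.29) and HEY1 by 3.86 (SE 0.30). TNFRSF17, which encodes the plasma cell receptor BCMA, had a log2 fold change of -2.41 (SE 0.26), METAP1D of -3.08 (SE 0.22) and DUS3L of -2.92 (SE 0.26). MYC was lower in 4 of 5 lines and the others had the same sign in 5 of 5, but CDKN1A hardly changed in SUDHL4 (0.14). The same test called 5790 of 13177 genes, 3038 higher and 2752 lower, and 1106 without the block. Scaling by library totals gave 3510 higher and 2300 lower, and a 2-fold limit 1246 higher and 880 lower.

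Of 16 tested members of the HDAC inhibitor response list, 9 rose at 6 h with pracinostat and with vorinostat 12, with the same counts adjusted over the list alone. KDM5B, a histone demethylase gene, rose by 1.84 (SE 0.30) with pracinostat and 2.34 (SE 0.31) with vorinostat. In camera the list had an adjusted p of 0.00741 and 0.00102, and an adjusted p = 0.537 and 0.357 with an estimated correlation. Of 6 tested CDK inhibitor genes 5 rose under each drug, also when adjusted over the list alone. CDKN2B, encoding p15, rose by 3.06 (SE 0.28) and 3.43 (SE 0.30). This list had adjusted p of 0.00588 and 0.0127 in camera, and an adjusted p = 0.162 and 0.193 with an estimated correlation. Among 11 HDAC genes, 3 rose and 1 fell with pracinostat, and 2 rose and 1 fell with vorinostat, the same adjusted over the list alone. HDAC11 rose by 2.07 (SE 0.43) and 2.15 (SE 0.45), HDAC3 by 0.54 (SE 0.10) and 0.78 (SE 0.11), and HDAC7 changed by -0.81 (SE 0.20) and -0.80 (SE 0.21). The level of HDAC11 was low, with a mean log2 CPM of 1.66 over the 6 h libraries and 1.70 over those of 14 days. HDAC1 stood at -0.02 (SE 0.12) and -0.17 (SE 0.12), neither called. HDAC5 was called with pracinostat alone, at 0.60 (SE 0.20), and lost that call without OCILY1, SUDHL6 or TOLEDO (adjusted p = 0.104, 0.0912 and 0.0738). Between the drugs HDAC5 differed by 0.09 (SE 0.22), not called.

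Histone acetyltransferase genes fell in 7 of 10 members with pracinostat and 8 of 10 with vorinostat, the same adjusted over the list alone. KAT5 (TIP60) changed by -1.71 (SE 0.16) and -1.79 (SE 0.18), KAT6B by -1.28 (SE 0.14) and -1.71 (SE 0.15), and CREBBP, a gene often mutated in DLBCL, by -0.81 (SE 0.14) and -0.86 (SE 0.15). The list's camera adjusted p was 0.000793 and 0.00102, with an adjusted p = 0.162 and 0.193 with an estimated correlation. Of 29 B-cell identity and receptor genes, 19 fell and 2 rose with pracinostat (21 and 2 adjusted over the list alone), and 20 fell and 2 rose with vorinostat (20 and 2 adjusted over the list alone). The surface receptor gene CD72 changed by -1.70 (SE 0.22) and -1.99 (SE 0.24), and IKZF3, the B-cell transcription factor gene of Aiolos, by -1.43 (SE 0.15) and -1.82 (SE 0.16). The tyrosine kinase gene LYN went the other way, with 0.41 (SE 0.11) and 0.73 (SE 0.11). Camera gave adjusted p of 1.13e-05 and 2.25e-05, and an adjusted p = 0.224 and 0.336 with an estimated correlation. Of 25 MYC and ribosome biogenesis genes, 18 fell under each drug (19 and 18 adjusted over the list alone), among them DKC1, which modifies ribosomal RNA, by -1.19 (SE 0.10) and -1.30 (SE 0.11). In camera the list had adjusted p of 2.4e-08 and 2.25e-05, and an adjusted p = 0.224 and 0.357 with an estimated correlation.

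Cell cycle and cell death genes were mixed at 6 h. Of all genes tested, 40.1% were called with pracinostat and 43.9% with vorinostat at that time. Member counts near or below these shares, those of the HDAC genes included, do not set a list apart. Of 25 G1/S and replication genes, 9 fell and 1 rose with pracinostat and 9 fell and 3 rose with vorinostat, the same adjusted over the list alone. Camera called this list with pracinostat (adjusted p = 0.0451), not without OCILY1, TOLEDO or WSUDLCL2, with an adjusted p = 0.84 with an estimated correlation, and not with vorinostat (adjusted p = 0.0501). Thymidylate synthase, TYMS, changed by -1.07 (SE 0.17) and -1.21 (SE 0.19). Among 25 G2/M genes, 3 rose with pracinostat (9 under scaling by library totals), and 1 rose and 5 fell with vorinostat (1 and 3 adjusted over the list alone). The proliferation marker MKI67 stood at -0.20 (SE 0.19) and -0.49 (SE 0.21), neither called, and without PFEIFFER it was called with vorinostat (adjusted p = 0.00919). Of 20 pro-apoptotic genes, 6 rose and 3 fell with pracinostat and 9 rose and 3 fell with vorinostat, the same adjusted over the list alone. APAF1, the core of the apoptosome, rose by 1.56 (SE 0.18) and 2.02 (SE 0.19), and BID changed by -0.88 (SE 0.14) and -1.05 (SE 0.14). Of 9 anti-apoptotic genes, 1 rose and 3 fell, and 2 rose and 4 fell, the same adjusted over the list alone. CFLAR, an inhibitor of caspase 8, changed by -0.98 (SE 0.14) and -1.28 (SE 0.15). Of 21 p53 target genes, 9 rose and 3 fell with pracinostat (11 and 3 adjusted over the list alone) and 12 rose and 3 fell with vorinostat (12 and 3 adjusted over the list alone). Camera called the p53 targets with vorinostat (adjusted p = 0.0381), not without TOLEDO, and with an adjusted p = 0.357 with an estimated correlation.

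**Figure D1:**
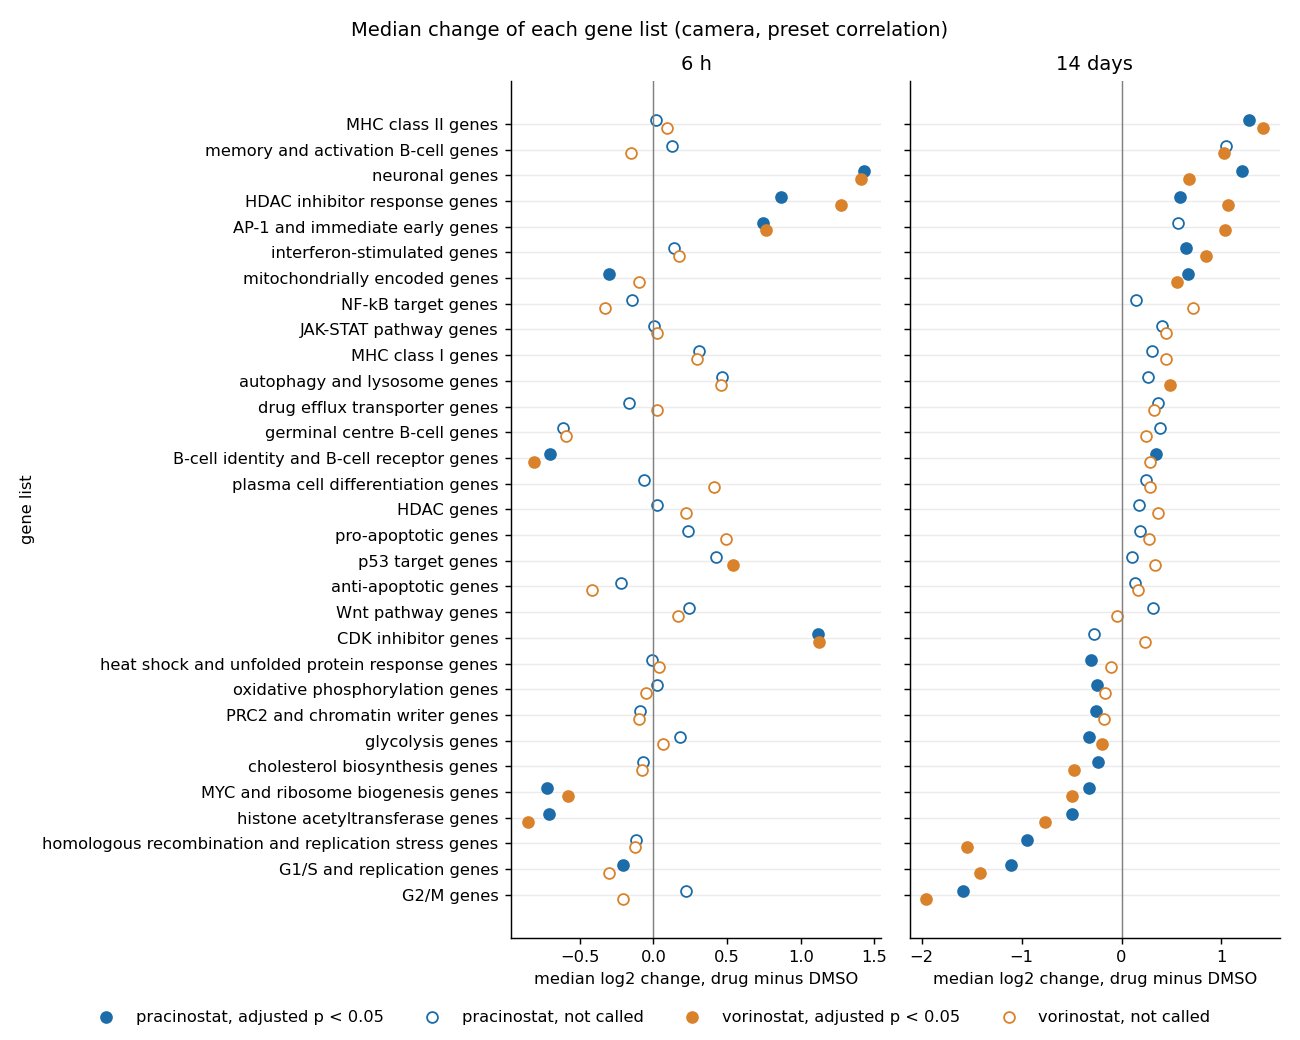
Median log2 change of the members of each list (x axis, drug minus DMSO) for the lists (y axis) with 5 or more tested members, at 6 h on the left and 14 days on the right. Filled points were called by camera at the preset correlation and open points were not; no list of these comparisons was called with an estimated correlation. G2/M genes lie lowest at 14 days, at -1.58 with pracinostat and -1.95 with vorinostat.

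The comparison of pracinostat with DMSOP at 14 days asked which transcripts stood apart after long exposure. Of 25 DNA replication genes 16 fell, of 22 DNA repair genes 16 fell, and of 13 MHC class II genes 11 rose (21, 17 and 12 adjusted over the list alone). Camera called these lists and the G2/M genes at the preset correlation and 0 of 31 lists with an estimated correlation. All 25 G2/M genes fell (25 adjusted over the list alone), among them KIF20A, a kinesin of cytokinesis, by a log2 fold change of -1.79 (SE 0.33, n = 5). TERT (ENSG00000164362, GRCh38 chromosome 5, 1253147 to 1295069), the catalytic subunit of telomerase, changed by -2.40 (SE 0.38). HLA-DMA (ENSG00000204257, chromosome 6, 32948613 to 32969094), which loads peptides onto MHC class II molecules, rose by 2.11 (SE 0.28). CDKN1A rose by 2.08 (SE 0.53) and HDAC11 by 2.34 (SE 0.49). All of these had the same sign in 5 of 5 lines, but CDKN1A hardly changed in PFEIFFER (0.06, against 3.69 in OCILY1).

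The same test called 3167 of 14037 genes with pracinostat at 14 days, 1733 higher and 1434 lower. Scaling by library totals turned that split to 1499 higher and 1727 lower, and a 2-fold limit gave 1175 higher and 302 lower. Without the block it called 8, and without OCILY1, PFEIFFER or SUDHL4 1970, 1424 and 1793 genes. Without OCILY1 or WSUDLCL2, CDKN1A was not called (adjusted p = 0.0884 and 0.0558). With the mean of DMSOP and DMSOV as control the count was 5008.

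Vorinostat set against DMSOV at 14 days moved the same groups. All 25 G2/M genes fell (25 adjusted over the list alone), with KIF20A at -2.50 (SE 0.35, n = 5) and KIF14, another mitotic kinesin, at -2.72 (SE 0.36). MKI67 changed by -2.47 (SE 0.40), and TERT by -4.02 (SE 0.45), from 14.5 ± 10.6 CPM to 0.883 ± 0.925 CPM (SD, n = 5). SCD, the desaturase that makes monounsaturated fatty acids, changed by -2.54 (SE 0.41). HLA-DMA rose by 2.53 (SE 0.28) and CDKN1A by 3.13 (SE 0.55), and all of these changed the same way in 5 of 5 lines. The same test called 5274 of 14037 genes, 2864 higher and 2410 lower, and 696 without the block. Scaling by library totals turned the split to 2308 higher and 2931 lower and moved the median of all genes from 0.12 to 0.01, and a 2-fold limit gave 1645 higher and 663 lower.

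At 14 days the G2/M list had camera adjusted p of 1.63e-15 with pracinostat and 9.89e-16 with vorinostat, and an adjusted p = 0.264 and 0.358 with an estimated correlation. MKI67 changed by -1.58 (SE 0.38) with pracinostat and was not called without PFEIFFER (adjusted p = 0.0556). Of 25 G1/S and replication genes, 16 fell with pracinostat and 20 with vorinostat (21 and 21 adjusted over the list alone). CDC45, a part of the replicative helicase, changed by -2.04 (SE 0.42) and TYMS by -2.06 (SE 0.43) with vorinostat. With pracinostat CDC45 and TYMS stood at -1.59 (SE 0.40) each, and neither was called without PFEIFFER (adjusted p = 0.0539 and 0.0738). Camera gave adjusted p of 1.12e-09 and 1.13e-10, and an adjusted p = 0.347 and 0.358 with an estimated correlation. Of 22 homologous recombination and replication stress genes, 16 fell with pracinostat and 18 with vorinostat (17 and 19 adjusted over the list alone). RAD54L, a DNA translocase, changed by -1.64 (SE 0.31) and -2.13 (SE 0.32). By camera, adjusted p was 8.84e-09 and 1.11e-10, and an adjusted p = 0.264 and 0.312 with an estimated correlation. Mitochondrially encoded transcripts, whose share of the counts can move with RNA quality, were higher in the same libraries and are described with the DMSO sets.

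Of 13 MHC class II genes at 14 days, 11 rose with pracinostat and 12 with vorinostat (12 and 12 adjusted over the list alone), with median log2 fold changes of 1.27 and 1.42. Camera gave adjusted p of 3.99e-05 and 0.000132, and an adjusted p = 0.264 and 0.312 with an estimated correlation. CIITA, the master regulator of MHC class II transcription, rose by 1.82 (SE 0.44) with vorinostat. Of 19 memory and activation B-cell genes, 5 rose with pracinostat and 9 with vorinostat (6 and 9 adjusted over the list alone). CCR7, the homing receptor for lymph nodes, rose by 4.14 (SE 0.68) with vorinostat. Camera called this list with vorinostat (adjusted p = 0.0312), not without WSUDLCL2, with an adjusted p = 0.409 with an estimated correlation. Of 29 B-cell identity genes, 6 rose and 0 fell with pracinostat, and 7 rose and 1 fell with vorinostat, the same adjusted over the list alone. FCER2 (CD23), the low-affinity IgE receptor, rose by 4.15 (SE 0.75) and 4.68 (SE 0.79), and PRKCB, a kinase of B-cell receptor signalling, by 3.33 (SE 0.64) and 3.28 (SE 0.64). Camera called the B-cell list with pracinostat (adjusted p = 0.0198), not without SUDHL4, with an adjusted p = 0.463 with an estimated correlation. Markers of other cell types moved in these libraries too. All 3 tested myeloid markers rose under both drugs, at mean levels of 4.54 CPM for ITGAM, 6.69 CPM for CSF1R and 2.12 CPM for CD33 over the drug libraries. In the DMSO libraries of 14 days their means were 0.0878, 0.423 and 0.105 CPM, near or under the counting floor. Such genes pass the filter through the drug libraries, so the count of 3 of 3 rising is no evidence by itself. The other 10 of 13 myeloid markers are not in the table, and their absence excludes nothing.

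HDAC inhibitor response genes rose at 14 days in 4 of 16 members with pracinostat and 8 with vorinostat (4 and 9 adjusted over the list alone). Camera gave this list adjusted p of 0.0198 and 0.00257, and an adjusted p = 0.257 and 0.131 with an estimated correlation. HDAC11 rose by 2.92 (SE 0.51) with vorinostat. Of 11 HDAC genes, 1 rose with pracinostat and 2 with vorinostat, the same adjusted over the list alone. Histone acetyltransferase genes fell in 6 and 8 of 10 members (6 and 9 adjusted over the list alone), KAT6B by -1.39 (SE 0.19) with vorinostat. In camera the list had adjusted p of 0.000848 and 0.000132, and an adjusted p = 0.264 and 0.312 with an estimated correlation. Of 20 PRC2 and chromatin writer genes, 3 fell and 1 rose with pracinostat (3 and 0 adjusted over the list alone) and 7 fell and 1 rose with vorinostat (7 and 1 adjusted over the list alone). EZH2, the PRC2 methyltransferase gene, changed by -0.69 (SE 0.17) with vorinostat, and stood at -0.34 (SE 0.17) with pracinostat, not called. Camera called the list with pracinostat (adjusted p = 0.0241), with an adjusted p = 0.264 with an estimated correlation. MYC and ribosome biogenesis genes fell in 6 and 14 of 25 members (7 and 15 adjusted over the list alone), CAD, the first enzyme of pyrimidine synthesis, by -1.08 (SE 0.16) with vorinostat. Camera gave adjusted p of 0.00116 and 0.000132, and an adjusted p = 0.569 and 0.409 with an estimated correlation. MYC itself stood at 0.02 (SE 0.19) and -0.03 (SE 0.19) and BCL2 at 0.14 (SE 0.20) and 0.17 (SE 0.21), none called.

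**Figure D2:**
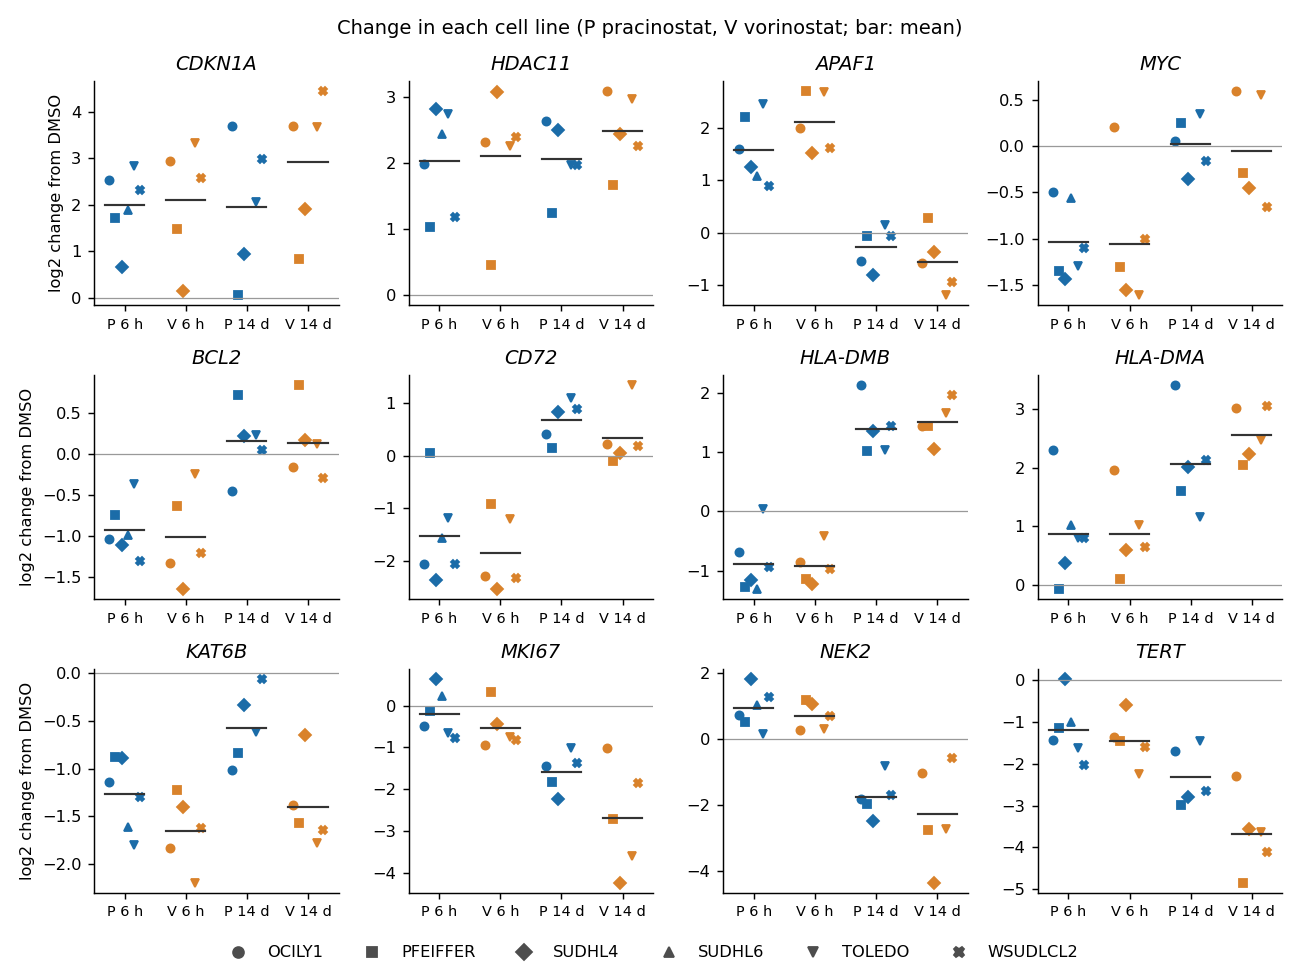
Log2 change from DMSO (y axis) of 12 genes in each line (marker shape) for pracinostat (P, blue) and vorinostat (V, orange) at 6 h and 14 days, with the mean as a bar. MYC and BCL2 lie below 0 at 6 h and around 0 at 14 days, apart from MYC in OCILY1 with vorinostat at 6 h, and HLA-DMB changes from mostly below 0 to above 0 in each line.

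The interaction of drug and time asked which effects differed between 14 days and 6 h. HLA-DMB, the partner of HLA-DMA, had an effect 2.32 (SE 0.26) higher at 14 days with pracinostat, on the log2 scale. With vorinostat it was 2.47 (SE 0.28, n = 5) higher. The pracinostat contrast took 6 lines at 6 h and 5 at 14 days, since SUDHL6 has no 14 day library. Blocks of line and time together do not pair a line's effects at 6 h with those at 14 days. The effect on CD72 was higher by 2.36 (SE 0.37) and 2.40 (SE 0.39), that on BCL2 by 1.05 (SE 0.26) and 1.15 (SE 0.27), and that on MYC by 1.07 (SE 0.28) and 0.94 (SE 0.30). With vorinostat MYC was not called without PFEIFFER, SUDHL4 or TOLEDO (adjusted p = 0.0636, 0.0569 and 0.198). The effect on APAF1 moved by -1.85 (SE 0.27) and -2.60 (SE 0.28), that on CDKN2B by -3.07 (SE 0.52) and -2.43 (SE 0.55), and that on the DNA methyltransferase gene DNMT3B by -2.97 (SE 0.44) and -3.12 (SE 0.47). CDKN1A differed by 0.04 (SE 0.63) and 0.91 (SE 0.66), neither called.

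The effect of time differed for 2986 of 15420 genes with pracinostat, 1470 higher and 1516 lower at 14 days, and for 3605 with vorinostat, 1722 higher and 1883 lower. Scaling by library totals gave 1028 higher and 2316 lower for pracinostat and 1256 higher and 2573 lower for vorinostat, and moved the medians of all genes from 0.06 to -0.09 and from 0.09 to -0.07. A 2-fold limit gave 850 higher and 569 lower, and 1060 higher and 817 lower. Without the block 75 and 252 genes were called, and without SUDHL4 1599 with pracinostat. Of 29 B-cell identity genes, 21 moved up with pracinostat, and 19 up and 1 down with vorinostat (24, and 22 and 1, adjusted over the list alone). Their camera adjusted p was 3.39e-09 and 1.16e-07, and an adjusted p = 0.0504 and 0.147 with an estimated correlation. Of 13 MHC class II genes, 10 and 12 moved up (11 and 13 adjusted over the list alone), with camera adjusted p of 2.96e-05 and 6.44e-06, and an adjusted p = 0.0819 and 0.147 with an estimated correlation. Of 25 G2/M genes, 25 and 24 moved down (25 and 25 adjusted over the list alone), with camera adjusted p of 3.69e-15 and 4.87e-15, and an adjusted p = 0.352 and 0.327 with an estimated correlation. Of 6 CDK inhibitor genes, 4 moved down with pracinostat and 2 with vorinostat (5 and 3 adjusted over the list alone). Camera called this list with pracinostat (adjusted p = 0.000851), and it held at an adjusted p = 0.0198 with an estimated correlation. Across 12967 genes tested at both times, fold changes at 6 h and 14 days had a Pearson r of 0.419 and a Spearman rho of 0.318 with pracinostat, and 0.483 and 0.424 with vorinostat, and genes are not independent replicates. Of the genes raised by pracinostat at 6 h, 630 were also raised at 14 days, where independence gives 315, and 151 were lowered. With vorinostat 1080 were raised at both times, where independence gives 585, and 236 went from raised to lowered.

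The comparison of the drugs with each other asked where these structurally related compounds differed, at doses that the labels do not give. At 6 h MED18, a subunit of the Mediator complex (ENSG00000130772, chromosome 1, 28329002 to 28335967, GRCh38), was higher with pracinostat than with vorinostat by 1.11 (SE 0.16) on the log2 scale in 5 of 5 lines. NXF1, the main exporter of messenger RNA (ENSG00000162231, chromosome 11, 62792123 to 62806302), differed by -0.79 (SE 0.12) in 5 of 5 lines. These were the 2 genes called of 13177 (adjusted p = 0.0364 each). Leaving out any line, the block or the WSUDLCL2 pracinostat library left 0 genes called by edgeR. The leave-one-out values were 0.99 to 1.24 for MED18 and -0.87 to -0.73 for NXF1. Other scalings, filters, a fit of all libraries, limma on the deposited values and limma-voom called 2 genes each, MED18 and NXF1, and DESeq2 called 49, these among them. At an unadjusted p under 0.05 there were 1214 genes, where 659 are expected by chance. CDKN1A differed by -0.17 (SE 0.27) at 6 h and by -1.05 (SE 0.73) between the drug effects at 14 days, and MKI67 by 0.29 (SE 0.21) and 0.89 (SE 0.53), none called. At 14 days edgeR called 0 of 14037 genes, DESeq2 0 and limma-voom 0. In edgeR 552 had an unadjusted p under 0.05, where 702 are expected by chance. The test was thus conservative here, and 0 calls do not show that the drug effects are alike. Its spread keeps the responses particular to a line, which both drugs shared as described below. The 95% interval of the difference, which rests on the same spread, lay within 2-fold for 10705 genes (81.2%) at 6 h. At 14 days it did so for 7406 (52.8%), so larger differences remain possible for the rest.

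Gene groups were called as different between the drugs in camera at the preset correlation alone. That setting also called 8 lists between the DMSO sets of 14 days, whose difference enters the 14 day comparison of the drugs. G2/M genes were higher with pracinostat than with vorinostat at 6 h, by a median of 0.41 (adjusted p = 1.24e-07, and an adjusted p = 0.72 with an estimated correlation), and at 14 days by a median of 0.40 (adjusted p = 4.78e-06, and an adjusted p = 0.60 with an estimated correlation). In total camera called 4 lists at 6 h and 14 at 14 days (9 without WSUDLCL2), and none of them with an estimated correlation or in fry. At 6 h, where both drugs share DMSO libraries, 2362 genes were raised and 2146 lowered by both, and 0 were called in opposite directions. At 14 days they shared 1403 raised and 1309 lowered genes, where independence gives 354 and 246, also with 0 in opposite directions. Across genes the fold changes of the drugs had a Pearson r of 0.929 and a Spearman rho of 0.905 at 6 h. Unchanged groups with shared DMSO libraries gave a simulated r of 0.465. The covariance, which unlike r keeps the size of the changes, was 0.447 at 6 h and 0.0239 in the simulation. When each drug's effect came from other lines, r was 0.587 to 0.784 over 20 splits. At 14 days, with separate DMSO libraries, r was 0.891 and rho 0.872, and 0.554 to 0.682 over 20 splits of the lines. Genes are not independent replicates, and no p-value is given for these.

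**Figure D3:**
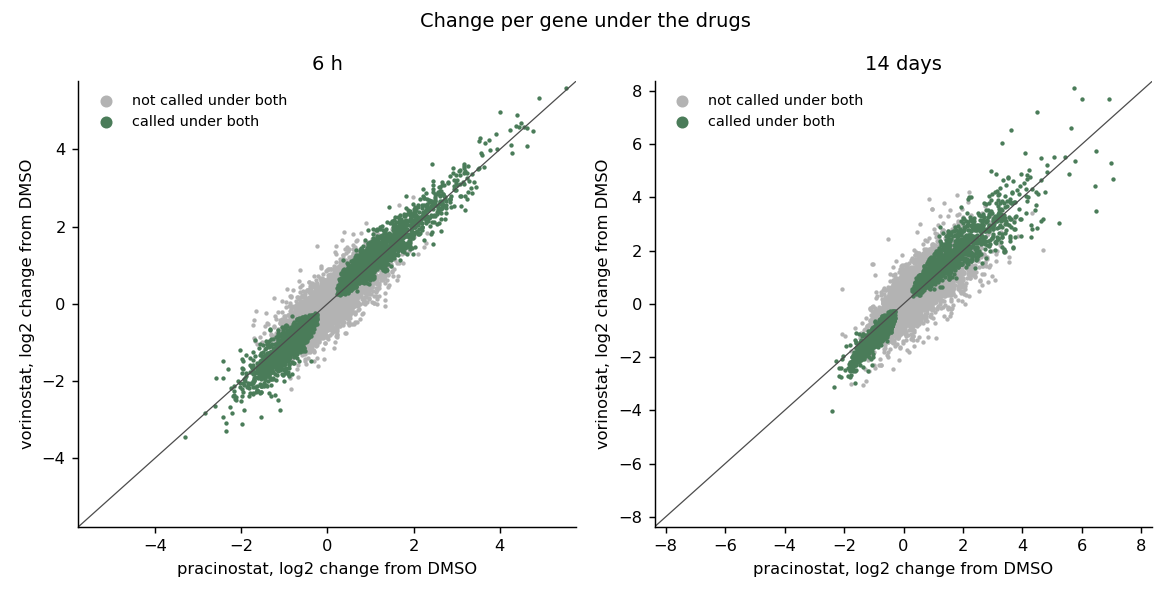
Log2 change from DMSO with vorinostat (y axis) against pracinostat (x axis) for each gene at 6 h (left, 13177 genes) and 14 days (right, 14037 genes), with the diagonal drawn. Green genes were called under both drugs and lie in the same direction under both.

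Lines differed in their response, and a line's own pattern was shared by both drugs. Per-line changes at 14 days correlated across genes between the drugs with a mean r of 0.768 in the same line and 0.416 between lines. With the mean over lines taken off, the mean r in the same line was 0.610. On these centred values an exact one-sided permutation of the line labels gave p = 0.00833, the smallest that 120 pairings allow, and 5 of 5 lines matched themselves best. Genes expressed in some lines alone were not set apart. The match therefore does not separate a line's response from its starting levels. At 6 h the mean r was 0.850 in the same line and 0.523 between lines, and the same permutation gave p = 0.00833 with 5 of 5 lines matched, which decides nothing there because the drugs share DMSO libraries. Genes at least 2-fold changed numbered 1208 (SUDHL6) to 1658 (WSUDLCL2) with pracinostat at 6 h and 1655 (WSUDLCL2) to 2042 (TOLEDO) with vorinostat. At 14 days they numbered 799 (TOLEDO) to 1998 (PFEIFFER) with pracinostat and 1129 (OCILY1) to 2704 (TOLEDO) with vorinostat. Between the DMSO sets they numbered 6 (PFEIFFER) to 276 (WSUDLCL2). These per-line counts rest on 1 library against 1 and have no test.

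**Figure D4:**
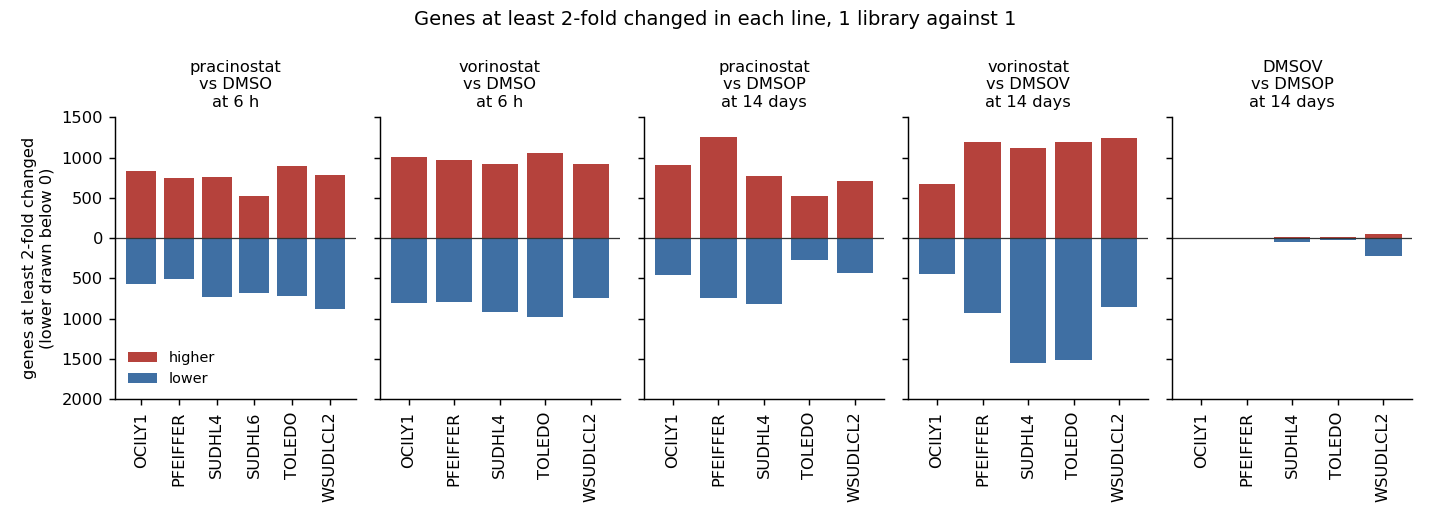
Number of genes at least 2-fold higher (red, above 0) or lower (blue, drawn below 0) in each cell line (x axis), for each drug against DMSO and for DMSOV against DMSOP. Drug libraries show 799 to 2704 such genes and the DMSO pairs 6 to 276.

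The DMSO sets of 14 days served as background. For MKI67 they differed by 0.06 (SE 0.36) and for CDKN1A by -0.51 (SE 0.55), DMSOV minus DMSOP. In edgeR's test 0 of 14037 genes were called, and DESeq2 and limma-voom called 0 each. In edgeR 83 had an unadjusted p under 0.05, where 702 are expected by chance. The test was thus conservative here, and 0 calls do not show that the sets are alike. Camera called 8 lists between the DMSO sets, 1 without WSUDLCL2 and 0 with an estimated correlation or in fry. Mitochondrially encoded genes, which give ribosomal RNA of the organelle and subunits of oxidative phosphorylation, took 8.97% ± 1.88 (SD, n = 5) of the counts in DMSOP and 10.2% ± 2.19 in DMSOV. With pracinostat at 14 days they took 14.4% ± 2.12 and with vorinostat 14.8% ± 3.15. The share rose over the own DMSO by 5.40 ± 1.48 points with pracinostat and 4.58 ± 2.74 points with vorinostat, in 5 of 5 lines. An exact two-sided paired permutation test gave p = 0.0625 for each, the smallest that 5 lines allow, and an adjusted p of 0.104 over 10 tests. Ribosomal protein genes also took a larger share at 14 days, by 2.81 ± 0.933 points with pracinostat and 4.77 ± 1.89 points with vorinostat in 5 of 5 lines, with the same p and adjusted p. Between the DMSO sets the mitochondrial share differed by 1.27 ± 0.69 points in 5 of 5 lines. Of 13 protein-coding mitochondrially encoded genes, 12 rose with pracinostat and 8 with vorinostat at 14 days (13 and 9 adjusted over the list alone), MT-ND6 by 0.97 (SE 0.20) and 0.92 (SE 0.20). By camera, adjusted p was 3.25e-07 and 0.00257, and an adjusted p = 0.257 and 0.358 with an estimated correlation. At 6 h 9 fell with pracinostat and 0 changed with vorinostat (10 and 0 adjusted over the list alone). Camera called the fall (adjusted p = 0.00132), with an adjusted p = 0.537 with an estimated correlation. Between the times 13 moved up with pracinostat and 9 with vorinostat (13 and 9 adjusted over the list alone). Camera called both (adjusted p = 5.34e-12 and 9.6e-05), with an adjusted p = 0.0198 and 0.26 with an estimated correlation.

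**Figure D5:**
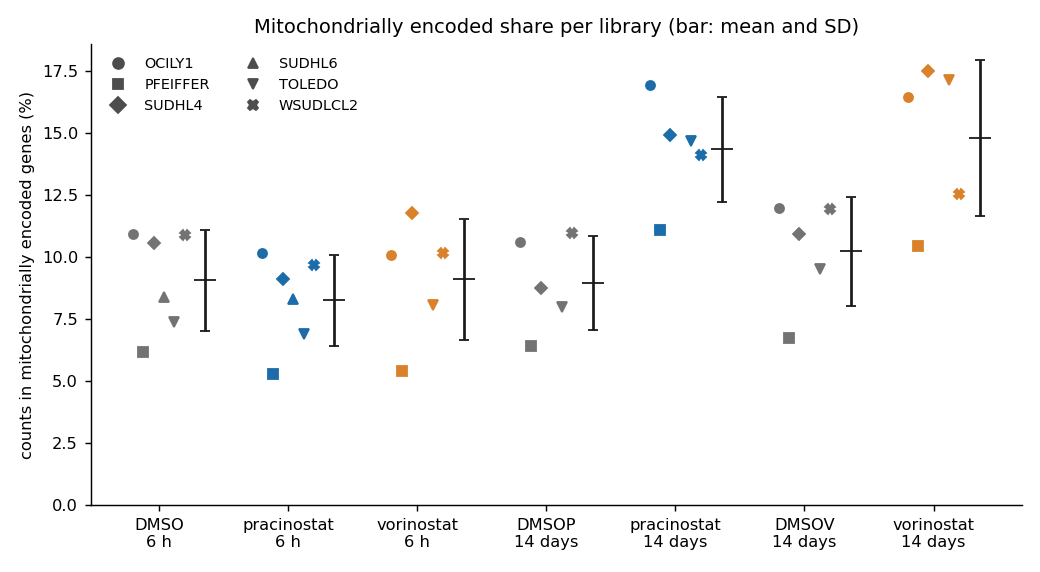
Share of counts in mitochondrially encoded genes (y axis, percent) per library for each group (x axis), with the cell line as marker shape and the mean and SD as a bar. The drug groups of 14 days have means of 14.4% and 14.8%, and the DMSO groups 8.97% to 10.2%.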

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

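The tests of the share of mitochondrially encoded transcripts against the DMSO difference and of cells of another type were chosen only after the result was seen.

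The effect of each drug differed between 6 h and 14 days in a tested interaction, for 2986 genes with pracinostat and 3605 with vorinostat, and this difference between the times is why both are listed here. Among 52 groups of library values tested for a library far from the others, 4 had one, where 2.6 are expected by chance. In OCILY1 vorinostat at 14 days raised 678 genes at least 2-fold, against 1122 in the nearest of the other 4 lines. In WSUDLCL2 228 genes were at least 2-fold lower in DMSOV than in DMSOP and 276 changed in all, against 43 and 62 in the nearest line. The SUDHL4 DMSO library of 6 h held 3.29 M counts (mega counts), against 6.72 M in the nearest of the 6.

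G2/M genes were lower at 14 days, with 25 of 25 members called under each drug. The technical explanations below were tested, and each is argued against as the whole cause. After all libraries were thinned to 3.19 M counts, 25 members were still called lower under each drug. Without mitochondrial and ribosomal protein genes the list's median, as a mean over lines, was -1.57 (SD 0.47) with pracinostat, the drug nearer 0, and -1.59 (SD 0.46) with these genes. With the trend on GC content and length removed it was -1.56. An effect of the drug, which the design names, may be the explanation and stays open as a hypothesis, with slower division and a loss of dividing cells not told apart by these values.

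MHC class II genes were higher at 14 days, in 11 of 13 members with pracinostat and 12 with vorinostat. Without mitochondrial and ribosomal protein genes the list's median, as a mean over lines, was 1.09 (SD 0.36) in the drug nearer 0, and with the trend on GC content and length removed it was 1.05, which argues against these as the whole cause. Cells of another type replacing most of the lymphoma cells are argued against by the B-cell identity genes, of which at most 1 of 29 was called lower under a drug. A small share of other cells stays open, since CSF1R, ITGAM and CD33 rose at mean levels of 6.69, 4.54 and 2.12 CPM, up to 29.5 CPM in a library. An effect of the drug on these genes stays open too, as a hypothesis.

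Mitochondrially encoded transcripts took a larger share of the counts at 14 days, by 5.40 points with pracinostat and 4.58 with vorinostat. The rise exceeded the difference of the line's DMSO libraries in 9 of 10 drug libraries, which argues against a difference between the DMSO sets as the whole cause. The exception was WSUDLCL2 with vorinostat, at 0.577 points against 0.978. Degraded RNA that loses long transcripts first cannot be told apart from a drug effect, since the change correlated with transcript length at a median Spearman rho of -0.0278, and under -0.1 in 2 of 10 libraries. The lowest value was -0.268, in TOLEDO with vorinostat.

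Other splits of the libraries were fitted as a check on the gene counts, each comparison in a fit of its own libraries alone, so that the real counts differ from those of the report. Swapping drug and DMSO within lines keeps the pairing of the libraries. For pracinostat at 6 h it argues against chance (4376 genes, highest other 0, 1 of 32 swaps as large). That is the smallest share that 32 swaps allow, not adjusted over the comparisons. The 16 such swaps are too few for a share under 0.05 for vorinostat at 6 h (4862, highest other 0, 1 of 16), pracinostat at 14 days (1950, highest other 0, 1 of 16) and vorinostat at 14 days (2680, highest other 0, 1 of 16). Splits that move libraries freely across lines break the pairing, so no conclusion about chance rests on them here. Of 100 such splits 1, the real one, was as large for pracinostat at 6 h (highest other 1370), vorinostat at 6 h (highest other 2), pracinostat at 14 days (highest other 2) and vorinostat at 14 days (highest other 0). For the interactions, splits that reassign the pairs of drug and DMSO to the times without regard to line gave the real counts of 2481 genes with pracinostat and 2221 with vorinostat in 1 of 40 each, with a highest other of 1, and swaps of the times within lines were not run. Where the real count was 0, every split is as large by construction and the splits decide nothing. This holds between the drugs at 6 h (100 of 100, highest other 670), between the drug effects at 14 days (40 of 40, highest other 45) and between the DMSO sets (100 of 100, highest other 1796). The splits with 670 and 1796 genes part the libraries of 1 line each, and since the line is a block the other lines add nothing to the contrast. Such counts point to a structure of the samples, whose cause was not tested.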

How the results depend on the processing

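The runs without mitochondrial and ribosomal protein genes, without the WSUDLCL2 pracinostat library of 6 h and the leave-one-out run of the line matching were chosen after the data were seen.

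Without the block of paired lines, genes called fell to 577 (pracinostat, 6 h), 1106 (vorinostat, 6 h), 8 (pracinostat, 14 days), 696 (vorinostat, 14 days), 75 and 252 (interactions of pracinostat and vorinostat) and 0 (pracinostat against vorinostat, 6 h). A 2-fold limit gave 1650, 2126, 1477, 2308, 1419, 1877 and 1 in that order. The mean of both DMSO sets as control gave 5008 genes for pracinostat at 14 days. Fits of each comparison's own libraries alone, made for the splits, called 4376 and 4862 genes at 6 h (pracinostat, vorinostat). At 14 days they called 1950 and 2680. The main fits, which share 1 spread per time, called 5289, 5790, 3167 and 5274 in that order. The smaller fits also hold fewer libraries. Pracinostat against vorinostat at 6 h gave 49 genes in DESeq2 and 0 in the 5 lines with all treatments, without the WSUDLCL2 pracinostat library or in leave-one-out runs (0 to 0).

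Camera with an estimated correlation called 0 lists in each of the 7 comparisons within a time. Fry called 15 and 14 lists at 6 h, 23 with vorinostat at 14 days, and 0 between the drugs at 6 h, between their effects at 14 days and between the DMSO sets.

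Median numbers of 2-fold genes per line moved with the minimum mean CPM. At 1 CPM they were 2568.5 and 2949 at 6 h, 2723 and 3638 at 14 days (pracinostat, vorinostat) and 265 between the DMSO sets, and at 20 CPM 712, 926, 585, 1148 and 3.

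Leave-one-out runs gave 1424 (without PFEIFFER) to 2766 genes for pracinostat at 14 days and 1599 (without SUDHL4) to 2892 for its interaction with time. Lists called were 1 (without WSUDLCL2) to 10 between the DMSO sets, 9 (without WSUDLCL2) to 15 between the drug effects at 14 days and 7 to 13 (without PFEIFFER) for vorinostat at 6 h. The cause was not tested for any of these.

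Of 760 results for named genes, 245 held their direction and side of the threshold under every alternative run. Of 13029 alternative values, 11707 were the same, 1259 weaker (487 of them without the block), 63 stronger and 0 reversed. A run with each SUDHL4 library of vorinostat at 14 days alone was not run, since the table has 1 such column. Depth limits low genes, since 3 counts were 0.336 to 0.941 CPM.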

Other observations

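No test of this part was chosen after its result was seen. Of all genes tested, 40.1% and 43.9% were called at 6 h and 22.6% and 37.6% at 14 days (pracinostat, vorinostat). Member counts near or below these shares do not set a list apart. Of 21 glycolysis genes at 14 days, 8 fell and 2 rose with pracinostat and 8 fell and 2 rose with vorinostat (8 and 2, and 8 and 3, adjusted over the list alone), with LDHA, which makes lactate, at -1.07 (SE 0.22) and -1.28 (SE 0.22). Camera called both (adjusted p = 0.00232 and 0.0314, the latter not without PFEIFFER), with an adjusted p = 0.264 and 0.395 with an estimated correlation. At 6 h 7 rose and 3 fell with pracinostat (10 rose under scaling by library totals) and 6 rose and 2 fell with vorinostat, the same adjusted over the list alone. Of 23 nuclear oxidative phosphorylation genes, 7 fell with pracinostat at 14 days, and 5 fell and 2 rose with vorinostat (9, and 8 and 2, adjusted over the list alone; 10 and 9 fell under scaling by library totals). Camera called the former (adjusted p = 0.000333), with an adjusted p = 0.298 with an estimated correlation, and at 6 h 1 to 2 fell and 1 rose under each drug (1 and 1 adjusted over the list alone). Of 19 cholesterol biosynthesis genes, 1 fell with pracinostat and 8 with vorinostat at 14 days, the same adjusted over the list alone. Camera called both (adjusted p = 0.0473, not without OCILY1, PFEIFFER or TOLEDO, and 0.00244), with an adjusted p = 0.569 and 0.409 with an estimated correlation. At 6 h 1 rose and 4 fell with pracinostat and 3 rose and 4 fell with vorinostat (1 and 3, and 3 and 4, adjusted over the list alone).

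Interferon-stimulated genes rose in 4 of 21 members with pracinostat and 9 with vorinostat at 14 days, the same adjusted over the list alone, IFIT2 by 2.28 (SE 0.54) with pracinostat. Camera called both (adjusted p = 0.0241 and 0.0313, neither without OCILY1 or PFEIFFER, the latter not without WSUDLCL2), with an adjusted p = 0.264 and 0.358 with an estimated correlation. At 6 h 3 rose and 2 fell of 18, and 4 rose and 1 fell, the same adjusted over the list alone. Of 14 MHC class I genes, 3 rose with pracinostat, and 5 rose and 3 fell with vorinostat at 14 days (4, and 6 and 3, adjusted over the list alone), and at 6 h 4 rose and 1 fell, and 3 rose and 2 fell, the same adjusted over the list alone. AP-1 and immediate early genes rose in 7 of 19 members at 6 h with pracinostat and 10 with vorinostat, with 1 lower under each (10 and 11 higher adjusted over the list alone), and in 1 and 10 of 18 at 14 days (1 and 10 adjusted over the list alone). JUN rose by 2.74 (SE 0.49) with vorinostat at 14 days. Camera called this list at 6 h (adjusted p = 0.0394, not without OCILY1 or TOLEDO, and 0.0127), with an adjusted p = 0.663 and 0.525 with an estimated correlation, and with vorinostat at 14 days (adjusted p = 0.019, not without PFEIFFER), with an adjusted p = 0.402 with an estimated correlation.

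Of 23 autophagy and lysosome genes, 12 rose and 4 fell with pracinostat and 14 rose and 3 fell with vorinostat at 6 h (13 and 4, and 15 and 3, adjusted over the list alone). WIPI1, which acts in autophagosome formation, rose by 0.94 (SE 0.18) and 1.57 (SE 0.19). At 14 days 2 rose, and 10 rose and 1 fell, the same adjusted over the list alone. Camera called the list with vorinostat at 14 days (adjusted p = 0.00578), with an adjusted p = 0.358 with an estimated correlation. Neuronal genes rose in 7 of 12 members under each drug at 6 h (7 and 7 adjusted over the list alone) and in 6 and 4 of 13 at 14 days (7 and 4 adjusted over the list alone). KIF5C, a kinesin of axons, rose by 2.14 (SE 0.16) and 2.18 (SE 0.17) at 6 h. Camera called them in all 4 comparisons (adjusted p = 0.0265, 0.0205, 0.00229 and 0.0233), with an adjusted p = 0.537, 0.357, 0.27 and 0.395 with an estimated correlation. These calls were lost without TOLEDO for pracinostat at 6 h and without OCILY1 or WSUDLCL2 for vorinostat at 14 days.

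Of 22 germinal centre genes, 1 rose and 9 fell with pracinostat and 3 rose and 9 fell with vorinostat at 6 h (3 and 10, and 3 and 9, adjusted over the list alone), and at 14 days 3 rose and 1 fell, and 5 rose and 2 fell (2 and 1, and 5 and 2, adjusted over the list alone). BCL6, the master regulator of the stage, stood at -0.49 (SE 0.32) with pracinostat at 6 h and 0.07 (SE 0.32) at 14 days, neither called, and without TOLEDO it was called at 6 h (adjusted p = 0.000839). Of plasma cell genes, 4 rose and 5 fell, and 4 rose and 4 fell of 14 at 6 h (5 and 5, and 4 and 4, adjusted over the list alone), with a median of -0.06 and a mean of 0.20 with pracinostat, and 0 and 4 of 13 rose at 14 days (0 and 4 adjusted over the list alone). Of NF-kB targets, 2 rose and 4 fell, and 3 rose and 6 fell of 18 at 6 h (2 and 4, and 4 and 7, adjusted over the list alone), and 3 rose and 1 fell, and 6 rose and 1 fell of 19 at 14 days, the same adjusted over the list alone. Of 16 JAK-STAT genes, 3 rose and 2 fell, and 4 rose and 2 fell at 6 h, and 1 and 4 rose at 14 days (1 and 1 adjusted over the list alone, and otherwise the same). Of Wnt genes, 5 rose and 1 fell, and 7 rose and 3 fell of 22 at 6 h (5 and 1, and 8 and 3, adjusted over the list alone), and 1 rose and 1 fell, and 1 rose and 2 fell of 23 at 14 days (1 and 1, and 0 and 2, adjusted over the list alone).

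Of 23 heat shock genes, 4 rose and 2 fell, and 7 rose and 1 fell at 6 h, the same adjusted over the list alone, and 3 fell, and 2 rose and 4 fell at 14 days (2, and 2 and 4, adjusted over the list alone). Camera called them lower with pracinostat at 14 days (adjusted p = 0.0305, not without PFEIFFER or TOLEDO), with an adjusted p = 0.521 with an estimated correlation. Of drug efflux genes, 3 rose and 1 fell of 12 under each drug at 6 h, and 4 rose and 3 fell, and 4 rose and 4 fell of 10 at 14 days (3 and 1 each, 5 and 3, and 5 and 4, adjusted over the list alone). ABCB1, which encodes P-glycoprotein, rose by 3.62 (SE 0.94) and 3.17 (SE 0.95) at 14 days and was not called without PFEIFFER (adjusted p = 0.0612 and 0.0559). Of metallothionein genes, 1 and 2 of 5 rose at 6 h and 1 and 2 of 3 at 14 days (1, 2, 2 and 3 adjusted over the list alone). Of p53 targets at 14 days, 4 rose and 2 fell, and 8 rose and 2 fell of 21, and of CDK inhibitor genes 1 of 6 rose under each drug, the same adjusted over the list alone. Of pro-apoptotic genes at 14 days 3 rose and 1 fell, and 5 rose and 2 fell of 20 (4 and 1, and 5 and 2, adjusted over the list alone), and 1 of 9 anti-apoptotic genes rose under each drug, also adjusted over the list alone. Of MHC class II genes at 6 h, 1 rose and 3 fell, and 1 rose and 2 fell of 13, of homologous recombination genes 2 rose and 6 fell of 22 under each drug, and of memory genes 2 rose and 3 fell, and 3 rose and 1 fell of 17, all the same adjusted over the list alone. Of PRC2 and chromatin writer genes at 6 h, 5 rose and 6 fell, and 4 rose and 5 fell of 20 (6 and 7, and 4 and 5, adjusted over the list alone). Of other cell markers at 14 days, 1 and 0 of 3 T-cell markers, 1 of 4 fibroblast markers under each drug and 0 of 1 epithelial marker rose (2 and 0, 1, and 0 adjusted over the list alone), and 0 of 9 erythroid markers were tested.

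A hypothesis that the drug effect at 6 h depends on a gene's level in untreated cells was tested against the level in DMSO libraries of 14 days. Spearman rho was below 0 in all 11 line and drug pairs, from -0.329 to -0.0328 with a median of -0.187, and under the limit of -0.1, set for every pair before the test, in 7. Among the 1297 genes of lowest level 381 rose and 42 fell with pracinostat, and 369 rose and 43 fell with vorinostat. Among the 1297 of highest level 145 rose and 399 fell, and 174 rose and 418 fell. The genes of lowest level had a median of 0.268 log2 CPM in DMSO at 14 days. Some may have passed the filter only through libraries where they were high, drug libraries included, and they had little room to fall. Their excess of rises, which also enters rho, therefore decides nothing. A dependence on level may hold and stays open, since 4 pairs did not reach the limit. A hypothesis that long intergenic non-coding genes rise more often than protein-coding genes of the same level is argued against at 6 h, where the share of rises among changed genes differed by -19.2 points with pracinostat and -23.6 points with vorinostat. At 14 days this share differed by 6.53 and 5.44 points, while 67 of 474 tested non-coding genes rose against 473 of 2185 protein-coding genes with pracinostat, and 114 against 607 with vorinostat.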
